A study of Arabidopsis thaliana with 9 samples.

How the data were processed

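Total RNA from the vegetative part of seedlings grown on MS medium was extracted with an RNeasy plant kit and hybridised to Affymetrix ATH1 arrays, per the labels' protocols. ATH1 arrays carry sets of short oligonucleotide probes for most annotated Arabidopsis genes. The 9 arrays fall into 3 genotypes with 3 biological replicates each, per the labels. The deposited values are log2 expression values that the authors made with RMA, per the submitters' processing notes. RMA corrects background, quantile-normalises the arrays and summarises probes on the log2 scale, so it gives the arrays nearly the same distribution, compresses changes of dim genes and hides a change shared by all genes. The version, the chip definition and the set of arrays normalised together are not given in the sources used here. The table has 1 row for each of 20777 AGI locus codes, so probes had been summarised per locus. It holds no control probe sets, detection calls or scan dates, so signal over background could not be judged per array, and no batch could be tested. Names came from a RefSeq gene table of the assembly TAIR10.1, in which 20508 of the 20777 loci were found, and otherwise from the gene lists or the locus code. No genome build is named in the sources used here, and no coordinates are given. Array medians lay between 6.35 and 6.41, lower quartiles between 4.28 and 4.42, with the highest in 35S::JAW replicate 2, and no pair of arrays held identical values. The median SD within a genotype was 0.089.

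Differences were tested in R 4.3.3 with limma 3.58.1, by lmFit with 1 mean per genotype over all 9 arrays and eBayes with a constant prior variance (6 residual and 5.04 prior degrees of freedom). Tests were two-sided, with Benjamini-Hochberg adjustment over all loci of a comparison, and a locus past an adjusted p of 0.05 is said to be called, to rise or to fall. No dim locus was left out. The comparisons were each line against wild type, the lines against each other and an F test over the genotypes. The design had been written for probe sets, and was applied to loci. On simulated data with 200 changed genes, the comparison of 35S::JAW with wild type over 20777 loci recovered 88% of changes of 0.5 and 100% of changes of 1 on the log2 scale, and 9.2% of 207 calls were unchanged genes. With no change simulated, the comparison of 35S::GA20OX with wild type gave 0 calls. This was a single draw with independent noise for each gene, so it does not show how many calls correlated noise gives. In 100 simulations that kept the correlation between genes seen in the residuals, up to 327 loci were higher in both unchanged lines. Up to 433 were lower in both. All their noise was drawn from 6 residual effects. Correlations that arose by chance in these were kept too, so the counts may be too high.

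Lists of genes were fixed before the data were examined: 34 lists with 460 loci, of which 420 were measured. They cover gibberellin, DELLA, TCP, boundary, GRF, jasmonate, cell cycle, cell wall, photosynthesis, flavonoid, auxin, cytokinin, brassinosteroid, glucosinolate, defence, senescence, flowering, clock, handling and heat genes, and markers of trichomes, stomata, xylem and phloem, roots, flowers and seeds. Some genes belong to 2 lists. Each list was tested against the other loci with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry, which asks whether a list moves on balance one way without comparing it with other genes. Counts of list members are over all loci, and also adjusted over the list alone.

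Genes were named by a rule also fixed before: the GA20OX genes and the 5 TCP targets, the 10 highest and 10 lowest called loci of each line without overlap between arrays, 5 and 5 between the lines, up to 4 called members per list or at most 2 uncalled ones, and 5 loci for each way of being called in both lines. GRF5 was named in addition because the series text mentions it. Alternatives were cyclic loess between arrays, centring on array medians, leaving out the dimmest 40% of loci, an intensity trend with a robust prior, array weights, the replicate number as a block, a 2-fold minimum, an adjusted p of 0.01, fits to the 6 arrays compared and leaving out each array. Overlaps between the lines were set beside 100 simulations of unchanged lines. In these all 9 arrays were redrawn from the residuals, with the correlation between genes kept, and both lines shared the 3 simulated control arrays.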

Results

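Transcript levels were measured in the vegetative part of Arabidopsis thaliana Col-0 seedlings at growth stage 1.03, with 3 Affymetrix ATH1 arrays for each of 3 genotypes: wild type, 35S::GA20OX and 35S::JAW. The 35S promoter drives strong expression in most tissues. GA20OX denotes gibberellin 20-oxidase, an enzyme of gibberellin synthesis, and JAW is the locus of microRNA miR319a, whose product directs cleavage of the transcripts of 5 TCP transcription factor genes that restrain growth at leaf margins. The series concerns different routes to larger leaves. The 9 arrays gave log2 expression values for 20777 loci, with array medians between 6.35 and 6.41. The replicates are labelled as biological, and the number of arrays (n = 3 per genotype) limits the precision: the median standard error (SE) of a log2 difference was 0.083. Pearson's r across loci, which are not independent replicates, was 0.9957 to 0.9976 between arrays of the same genotype. It was 0.995 to 0.9967 between wild type and 35S::GA20OX, 0.9911 to 0.9927 between wild type and 35S::JAW, and 0.9892 to 0.9919 between the transgenic lines.

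GA20OX1 and the TCP genes targeted by miR319 followed the labels on every array, and miR319a itself is not reported. GA20OX1 (AT4G25420) had a log2 value of 12.96 ± 0.04 (SD, n = 3) in 35S::GA20OX against 6.06 ± 0.07 in wild type, a difference of 6.90 ± 0.09 (SE), or 119.8-fold (limma adjusted p = 7.14e-12). In 35S::JAW, the 5 TCP genes fell. Their log2 differences from wild type were -3.43 ± 0.07 for TCP2 (AT4G18390), -3.23 ± 0.11 for TCP3 (AT1G53230), -2.92 ± 0.09 for TCP4 (AT3G15030), -2.54 ± 0.08 for TCP24 (AT1G30210) and -1.83 ± 0.10 for TCP10 (AT2G31070). The adjusted p lay between 1.73e-10 for TCP2 and 9.29e-07 for TCP10. In 35S::GA20OX the same 5 TCP genes differed from wild type by -0.20 to 0.02, and none passed. The other gibberellin 20-oxidase genes, GA20OX2 to GA20OX5, did not pass in 35S::GA20OX, where their log2 differences lay between -0.01 and 0.20. Their log2 values on those arrays were low, between 3.70 and 4.71. The series text also names a line overexpressing GRF5 (AT3G13960), a genotype that none of the 9 samples carries in its labels. The log2 difference of GRF5 from wild type was -0.11 in 35S::GA20OX, which did not pass, and -0.37 ± 0.10 in 35S::JAW (adjusted p = 0.0418, and up to 0.148 with 1 array left out).

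**Figure D1:**
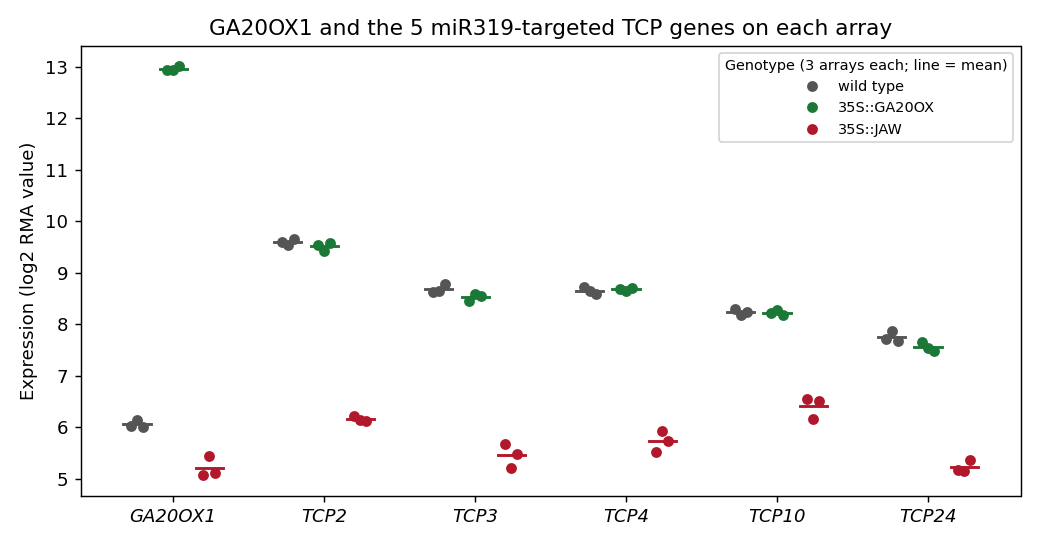
Log2 RMA expression values (vertical axis) of GA20OX1 and of the 5 TCP genes targeted by miR319 (horizontal axis) on each of the 9 arrays, with 1 point per array and a line at the mean of the 3 arrays of a genotype. GA20OX1 stands at 12.94 to 13.01 on the 35S::GA20OX arrays against 6.01 to 6.14 on the wild-type arrays, and each TCP gene lies lower on all 35S::JAW arrays than on any other array.

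The comparison of 35S::GA20OX with wild type asked which transcripts differed in seedlings overexpressing a gibberellin-synthesis enzyme. Of 20777 loci tested 34 were higher and 35 lower, 5 and 4 of them by at least 2-fold. GA3OX1 (AT1G15550), which makes bioactive gibberellin and is repressed by it, fell by 0.60 ± 0.07 (SE) on the log2 scale (adjusted p = 0.00482), and the DELLA repressor gene RGL2 (AT3G03450) rose by 0.62 ± 0.10 (adjusted p = 0.0287). Of 21 flavonoid and anthocyanin genes 5 fell (adjusted p = 0.168 for the list with an estimated correlation), among them chalcone synthase (CHS, AT5G13930) with -0.93 ± 0.13 and the anthocyanin glucosyltransferase UGT75C1 (AT4G14090) with -0.79 ± 0.12. Others that fell were GSTF12 (AT5G17220), needed for anthocyanin transport, with -0.76 ± 0.11, and UGT79B1 (AT5G54060) with -0.73 ± 0.13. The genes of aliphatic glucosinolate synthesis, the pathway of sulfur-rich defence compounds, had a mean log2 difference of 0.35 as a group, with none of 15 past the threshold over all loci (camera adjusted p = 3.53e-12, and adjusted p = 0.252 with an estimated correlation). Without wild type replicate 2 that mean was 0.23.

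After GA20OX1, the largest increase was in HFR1 (AT1G02340), a transcription factor of light signalling, which rose by 1.55 ± 0.15 (adjusted p = 0.00166). It was followed by AT4G17470 (1.45 ± 0.14), AT5G22460 (1.097 ± 0.087) and AT4G23680 (1.09 ± 0.09). The next were FMO GS-OX2 (AT1G62540), which oxidises glucosinolate side chains, with 0.96 ± 0.14, AT2G34810 with 0.87, DR4 with 0.83, the jacalin-related lectin gene JAL23 with 0.81 and CER1 (AT1G02205), an enzyme of wax alkane synthesis, with 0.78 ± 0.09. The strongest decreases were in AT3G20370 (-1.47 ± 0.16), AT4G36700 (-1.35 ± 0.24), the light-harvesting gene LHCB4.3 (-1.08 ± 0.09, adjusted p = 0.000496) and AT3G16530 (-1.02 ± 0.13). AT3G44970 (-0.93 ± 0.16), the pathogenesis-related gene PR4 (-0.92 ± 0.09, adjusted p = 0.00167) and AT1G52100 (-0.82 ± 0.12) completed the lowest 10 together with CHS, UGT75C1 and GSTF12. All 69 called loci had 3 transgenic arrays on the same side of all 3 wild-type arrays, as had 16.8% of all loci, where chance gives 10%.

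Camera with its preset correlation called 11 of 34 gene lists in 35S::GA20OX, 6 higher and 5 lower, and with an estimated correlation between genes it called none. Without 35S::GA20OX replicate 1 it called 7. The 15 measured aliphatic glucosinolate genes all had positive log2 differences, with none past the threshold over all loci and 12 when adjusted over the list alone. UGT74C1 (0.45 ± 0.11) and SOT17 (0.43 ± 0.12, and 0.27 without wild type replicate 2) were among them. Of 21 flavonoid and anthocyanin genes 5 fell, and 11 when adjusted over the list alone, with a mean of -0.31 (camera adjusted p = 3.48e-08, and adjusted p = 0.168 with an estimated correlation). The 12 stomatal lineage markers had a mean of -0.25, with 0 past the threshold over all loci and 5 lower when adjusted over the list alone (camera adjusted p = 2.78e-06, and adjusted p = 0.183 with an estimated correlation). In that list MYB60 (-0.58 ± 0.12) and SDD1 (-0.44 ± 0.10) had the largest differences. Among 12 genes known to be activated by DELLA proteins, GA3OX1 and the MYB gene AT3G11280 (-0.43 ± 0.06) fell. Adjusted over the list alone 1 was higher and 5 were lower, and the list mean was -0.17 (camera adjusted p = 0.000547, and adjusted p = 0.168 with an estimated correlation). GA3OX1 also belongs to the gibberellin synthesis list, which was not called.

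The 8 heat shock genes had a mean of 0.21 (camera adjusted p = 0.00137, and adjusted p = 0.168 with an estimated correlation), led by HSP70 (0.69 ± 0.18), with 1 higher when adjusted over the list alone. The 15 jasmonate response genes had a mean of 0.14 (camera adjusted p = 0.00218, and adjusted p = 0.215 with an estimated correlation), led by JAZ9 (0.40 ± 0.12), with 0 when adjusted over the list alone. The 8 D-type cyclin genes, which promote entry into the cell cycle, all had negative differences with a mean of -0.16 (camera adjusted p = 0.00225, and adjusted p = 0.252 with an estimated correlation), and CYCD3;3 had -0.27 ± 0.07. Of them 2 were lower when adjusted over the list alone. Of 24 auxin genes IAA6 (AT1G52830) rose by 0.61 ± 0.10, 2 were higher when adjusted over the list alone, and the mean was 0.12 (camera adjusted p = 0.0168, and adjusted p = 0.279 with an estimated correlation). That call ended without wild type replicate 3 and without 35S::GA20OX replicate 1, where the highest adjusted p was 0.172. The 12 xylem and phloem markers had a mean of 0.15, with 2 higher when adjusted over the list alone (camera adjusted p = 0.0239, and adjusted p = 0.361 with an estimated correlation), and LAC17 had 0.33 ± 0.09. That call ended without 35S::GA20OX replicate 1 and without replicate 3, with adjusted p up to 0.119.

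The 11 GRF and GIF genes, regulators of leaf cell number, had a mean of -0.11, with 2 lower when adjusted over the list alone (camera adjusted p = 0.0395, and adjusted p = 0.252 with an estimated correlation), led by GIF1 (-0.41 ± 0.10). The call ended without wild type replicate 1 or replicate 3 and without 35S::GA20OX replicate 1 or replicate 2, with adjusted p up to 0.127. The 27 expansin and xyloglucan endotransglucosylase genes, which loosen cell walls, had a mean of 0.08, with 3 higher when adjusted over the list alone (camera adjusted p = 0.044, and adjusted p = 0.215 with an estimated correlation), and EXPB1 had 0.40 ± 0.11 (0.26 without wild type replicate 2). This call was lost with any 1 of 5 arrays left out: wild type replicate 2, 35S::GA20OX replicates 1 and 2, and 35S::JAW replicates 1 and 2, with adjusted p up to 0.118. Of the lists not called, root markers had a mean of -0.13 (camera adjusted p = 0.0516), and passed with any 1 of 6 arrays left out: wild type replicates 1 and 2, 35S::GA20OX replicate 2 and each 35S::JAW replicate (lowest adjusted p = 0.0292). The S phase list passed without 35S::GA20OX replicate 3 (mean -0.07, adjusted p = 0.0318), and the defence list without wild type replicate 3 (mean -0.16, adjusted p = 0.033). Over all arrays, floral organ markers had a mean of 0.12 (0.0672), seed storage markers 0.04 (0.744), trichome markers -0.01 (0.852), and photosynthesis and chlorophyll genes -0.02 (0.381). G2 and M phase genes had a mean of 0 (0.994), S phase genes -0.04 (0.228) and cell cycle inhibitors 0.00 (0.926). Gibberellin synthesis genes, a list that leaves out the transgene GA20OX1, had a mean of -0.06 (0.269), and gibberellin perception genes 0.08 (0.16). The miR319-targeted TCP genes had -0.08 (0.225) and the CIN-type TCP genes without a miR319 site 0.01 (0.962). Boundary and KNOX genes had 0.07 (0.373), jasmonate synthesis genes 0.06 (0.269), cytokinin response genes -0.03 (0.544) and flowering and phase change genes -0.03 (0.831). Senescence and dark-induced genes had -0.09 (0.425), morning clock genes -0.06 (0.425), evening clock genes 0.02 (0.97), and touch, wound and cold genes -0.05 (0.425). Gibberellin deactivation genes had a mean of 0.03 and a median of -0.04 (0.926), and brassinosteroid synthesis genes a mean of -0.09 and a median of 0.03 (0.289). In the salicylic acid and defence list, which was not called (camera adjusted p = 0.215), PR5 (AT1G75040) fell by 0.37 ± 0.07.

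The count of loci called in 35S::GA20OX depended on single arrays and on the model. It was 102 higher and 103 lower with an intensity trend and robust prior, 55 and 53 without the dimmest 40% of loci, and 8 and 7 at an adjusted p of 0.01. With 1 array left out it was 11 higher and 11 lower without wild type replicate 3, 19 and 20 without wild type replicate 1, and 17 and 18 without wild type replicate 2. It was 16 and 20 without 35S::GA20OX replicate 1, 24 and 19 without replicate 2, and 21 and 16 without replicate 3. The calls of CHS, UGT75C1, UGT79B1, GSTF12, IAA6, RGL2, PR5, JAL23, FMO GS-OX2, AT3G11280, AT2G34810, AT3G44970, AT4G36700 and AT1G52100 were each lost with at least 1 array left out (adjusted p up to 0.184). Those of GA20OX1, HFR1, GA3OX1, CER1, LHCB4.3 and PR4 were lost in none of the 9 such fits.

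The comparison of 35S::JAW with wild type asked which transcripts differed where the miR319-targeted TCP genes were reduced. In all, 902 loci were higher and 827 lower, 67 and 101 of them by at least 2-fold. Of 13 genes of jasmonate synthesis 4 fell, led by the acyl-CoA oxidase gene ACX1 (AT4G16760) with -2.55 ± 0.09 (SE) and the lipoxygenase gene LOX2 (AT3G45140) with -2.06 ± 0.06. Of 24 auxin genes 12 fell and 1 rose, with IAA29 (AT4G32280) at -1.69 ± 0.21, the homeobox gene HAT2 (AT5G47370) at -1.67 ± 0.09 and IAA1 (AT4G14560) at -1.62 ± 0.10. Of 23 genes of DNA replication 6 fell, and of 6 genes of the evening phase of the circadian clock 4 fell, with both list calls lost with an estimated correlation (adjusted p = 0.117 and adjusted p = 0.349). TCP5 (AT5G60970) and TCP13 (AT3G02150), TCP genes of the same class without a miR319 site, rose by 0.60 ± 0.11 and 0.62 ± 0.11.

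The deepest decrease was in ELI3-1 (AT4G37980), a gene of the cinnamyl alcohol dehydrogenase family, which fell by 4.36 ± 0.06 on the log2 scale (adjusted p = 1.2e-11). AT3G16670 (-3.60 ± 0.23), PCC1 (-2.97 ± 0.39), AT1G51090 (-2.90 ± 0.20) and the receptor-like kinase gene CRK22 (-2.59 ± 0.13) also fell. The neighbouring loci AT1G31680 (-3.03 ± 0.09) and AT1G31690 (-2.99 ± 0.14) fell alike, and probes shared between similar loci were not checked. The largest increases were in AT5G01740 (2.32 ± 0.09, adjusted p = 3.41e-08), AZI1 (2.14 ± 0.39), AT2G05540 (2.13 ± 0.13), the sugar transporter gene SWEET1 (AT1G21460, 2.08 ± 0.07) and the asparagine synthetase gene ASN1 (AT3G47340, 2.04 ± 0.29). AT3G60290 (1.87 ± 0.11), AT4G21870 (1.86 ± 0.10), BT5 (1.79 ± 0.32), SCPL7 (1.71 ± 0.13) and the pathogenesis-related gene PR5 (1.70 ± 0.07) followed. GA20OX1, the transgene of the other line, fell by 0.85 ± 0.09 in 35S::JAW.

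Camera with its preset correlation called 12 of 34 lists in 35S::JAW, 3 higher and 9 lower, and 3 of the calls held with an estimated correlation. These were the miR319-targeted TCP genes, auxin genes and jasmonate synthesis. All 5 targeted TCP genes fell (5 when adjusted over the list alone), with a mean of -2.79 (camera adjusted p = 1.6e-19, and adjusted p = 0.00247 with an estimated correlation). Of 24 auxin genes 12 fell and 1 rose (15 and 2 when adjusted over the list alone), with a mean of -0.52 (camera adjusted p = 2.47e-10, and adjusted p = 0.0496 with an estimated correlation). Among them SAUR65 fell by 1.37 ± 0.15. Of 13 jasmonate synthesis genes 4 fell (4 when adjusted over the list alone), namely ACX1, LOX2, the allene oxide synthase gene AOS (-0.68 ± 0.07) and JAR1 (-0.63 ± 0.08). The list had a mean of -0.45 (camera adjusted p = 0.000187, and adjusted p = 0.0496 with an estimated correlation). Its median was only -0.17, with 9 negative and 4 positive members, so the mean rested largely on the 4 genes that fell. Of the 15 jasmonate response genes JAZ1 (-0.99 ± 0.14) and CLH1 (-0.43 ± 0.09) fell and JAZ6 (0.62 ± 0.10) and JAZ9 (0.52 ± 0.12) rose, and that list was not called (camera adjusted p = 0.82).

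All 23 S phase and DNA replication genes had negative differences, 6 fell and 11 did when adjusted over the list alone, with a mean of -0.20 (camera adjusted p = 1.34e-07, and adjusted p = 0.117 with an estimated correlation). The replication genes MCM5 (-0.43 ± 0.10) and PCNA1 (-0.37 ± 0.07), ETG1 (-0.35 ± 0.09) and the ribonucleotide reductase gene TSO2 (-0.35 ± 0.08) led that list. The 21 G2 and M phase genes had a mean of -0.07 (camera adjusted p = 0.105), with none past the threshold. Without wild type replicate 2 that list passed (mean -0.11, adjusted p = 0.0191). Of the 8 D-type cyclin genes CYCD4;1 fell by 0.37 ± 0.09, 3 were lower when adjusted over the list alone, and the mean was -0.17 (camera adjusted p = 0.0167, and adjusted p = 0.403 with an estimated correlation). That call was lost without 35S::JAW replicate 2 (mean -0.10, adjusted p = 0.152). Of the 15 cell cycle inhibitor and endocycle genes SMR1 fell by 0.67 ± 0.09 while SMR2 (0.66 ± 0.15) and KRP2 (0.26 ± 0.07) rose, and the list was not called (camera adjusted p = 0.919). Of the 6 evening clock genes 4 fell (4 when adjusted over the list alone): ELF4 by 1.26 ± 0.14, PRR3 by 0.76 ± 0.16, TOC1 by 0.44 ± 0.09 and GI by 0.39 ± 0.09. The list had a mean of -0.53 (camera adjusted p = 7.83e-05, and adjusted p = 0.349 with an estimated correlation). The 4 morning clock genes had a mean of 0.07 (camera adjusted p = 0.719), and none passed.

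Of the 11 senescence and dark-induced genes 4 rose (4 when adjusted over the list alone): ASN1, SEN1 (AT4G35770) by 1.39 ± 0.26, SAG21 by 1.21 ± 0.31 and NAP by 0.57 ± 0.15. The list had a mean of 0.55 (camera adjusted p = 0.0258, and adjusted p = 0.403 with an estimated correlation). Without wild type replicate 1 the list's adjusted p was 0.0675 and SAG21 had 0.79, and without 35S::JAW replicate 1 NAP had 0.36 (adjusted p = 0.0951). Of 21 flavonoid and anthocyanin genes 5 fell and 1, MYBL2, rose (5 and 3 when adjusted over the list alone). DFR, which makes leucoanthocyanidins, had -1.78 ± 0.16, GSTF12 -1.37 ± 0.11, UGT75C1 -1.14 ± 0.12 and UGT79B1 -1.07 ± 0.13. That list had a mean of -0.26 (camera adjusted p = 0.0258, and adjusted p = 0.408 with an estimated correlation), and its call was lost without wild type replicate 3, with a mean of -0.22 and an adjusted p of 0.0502. Its median was only -0.08, with 13 negative and 8 positive members, so the mean rested largely on the genes that fell. Of 15 aliphatic glucosinolate genes FMOGS-OX3 (-0.49 ± 0.11) and FMOGS-OX1 (-0.42 ± 0.12) fell (2 when adjusted over the list alone), with a mean of -0.19 (camera adjusted p = 0.00407, and adjusted p = 0.626 with an estimated correlation). That call was lost without wild type replicate 3 (mean -0.12, adjusted p = 0.0636), and without wild type replicate 2 the mean was -0.31. Beside these lists, the 12 xylem and phloem markers had a mean of -0.27, 1 fell (PP2-A1, by 0.27 ± 0.07) and 5 were lower when adjusted over the list alone (camera adjusted p = 0.00116, and adjusted p = 0.349 with an estimated correlation). Of the 13 gibberellin synthesis genes 4 rose (4 when adjusted over the list alone), led by GA2 (AT1G79460) with 0.62 ± 0.07, with GA20OX2 at 0.33, GA3 at 0.31 and GA20OX3 at 0.30. GA20OX2 and GA20OX3 were dim, with log2 values of at most 4.39 and 4.15 on the 35S::JAW arrays. The lower quartiles of the arrays lay between 4.28 and 4.42, and signal over background could not be judged. The gibberellin synthesis list had a mean of 0.15 (camera adjusted p = 0.0258, and adjusted p = 0.206 with an estimated correlation). Its call was lost without wild type replicate 3 or 35S::JAW replicate 2 (adjusted p up to 0.0542). The 3 CIN-type TCP genes without a miR319 site had a mean of 0.49, 2 rose, and 3 were higher when adjusted over the list alone (camera adjusted p = 0.00223, and adjusted p = 0.349 with an estimated correlation).

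Several lists that camera did not call in 35S::JAW held genes that moved in opposite directions. Of 13 cytokinin genes CKX4 (-1.37 ± 0.11) and ARR16 (-1.06 ± 0.12) fell while ARR5 (0.97 ± 0.17) and ARR6 (0.68 ± 0.15) rose. Of 9 brassinosteroid synthesis genes DWF4 (-1.09 ± 0.10) and CYP90D1 (-0.42 ± 0.09) fell while ROT3 (0.88 ± 0.09) and DWF1 (0.34 ± 0.07) rose. GRF3 (AT2G36400) rose by 0.83 ± 0.14, whereas GIF1 fell by 0.54 ± 0.10. The cell wall genes XTH22 (1.16 ± 0.30), XTH32 (0.89 ± 0.10) and EXPB3 (0.67 ± 0.16) rose and XTH17 fell by 0.85 ± 0.09. XTH22, which also belongs to the list of touch, wound and cold genes, rose there while CBF3 fell by 1.01 ± 0.18. The DELLA repressor genes RGL1 (-0.73 ± 0.09) and GAI (-0.42 ± 0.07) fell. Among defence genes WRKY54 (-1.40 ± 0.21) and WRKY70 (-1.21 ± 0.32) fell beside the increase of PR5. The flowering gene SOC1 (-0.85 ± 0.09), FUL (-0.45 ± 0.09) and SPL9 (-0.33 ± 0.08) fell. The stomatal lineage genes SPCH (0.64 ± 0.15) and TMM (0.50 ± 0.10) rose in a list with a mean of 0.12 (camera adjusted p = 0.217). Of the other markers, root markers had a mean of -0.15 (camera adjusted p = 0.0788, and 0.0397 without wild type replicate 1), trichome markers 0.03 (0.754), floral organ markers 0.05 (0.697), seed storage markers 0.07 (0.697), and photosynthesis and chlorophyll genes 0.00 (0.92). The touch, wound and cold genes had a mean of 0.33 (0.551), which rested on 35S::JAW replicate 1. On that array their mean difference from wild type was 0.95, against -0.04 on replicate 2 and 0.09 on replicate 3, and without it the list mean was 0.03 and XTH22 had 0.75 (adjusted p = 0.0546). Heat shock genes had a mean of 0.07 (0.697), boundary and KNOX genes -0.12 (0.211), and gibberellin deactivation genes -0.09 (0.533). Gibberellin perception genes had a mean of -0.10 (0.237), DELLA-activated genes 0.03 (0.89), expansin and xyloglucan endotransglucosylase genes 0.12 (0.258), defence genes -0.14 (0.186), flowering and phase change genes -0.07 (0.253), and brassinosteroid synthesis genes -0.06 (0.754). The mean, median and direction of the test differed in sign for GRF and GIF genes (mean 0.01, test lower, adjusted p = 0.82), cytokinin genes (mean -0.004, median 0.016, adjusted p = 0.876), cell cycle inhibitors (mean 0.02, median -0.02) and photosynthesis genes (test lower).

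The count in 35S::JAW fell by over 1.5 times without wild type replicate 3 (548 higher and 526 lower) and without wild type replicate 1 (589 and 546). The calls of GA3, GA20OX2, GA20OX3, GI, PRR3, PCNA1, MCM5, ETG1, TSO2, CYCD4;1, KRP2, SMR2, FMOGS-OX1, FMOGS-OX3, SAG21, NAP, PP2-A1, CLH1, JAZ9, ARR6, CYP90D1, DWF1, XTH22, EXPB3, WRKY70, SPCH, FUL and SPL9 were lost with at least 1 array left out (adjusted p up to 0.173). Those of the 5 targeted TCP genes, ELI3-1, ACX1, LOX2, IAA1, IAA29, HAT2, ELF4, DFR and SWEET1 were lost in none of the 9 such fits.

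**Figure D2:**
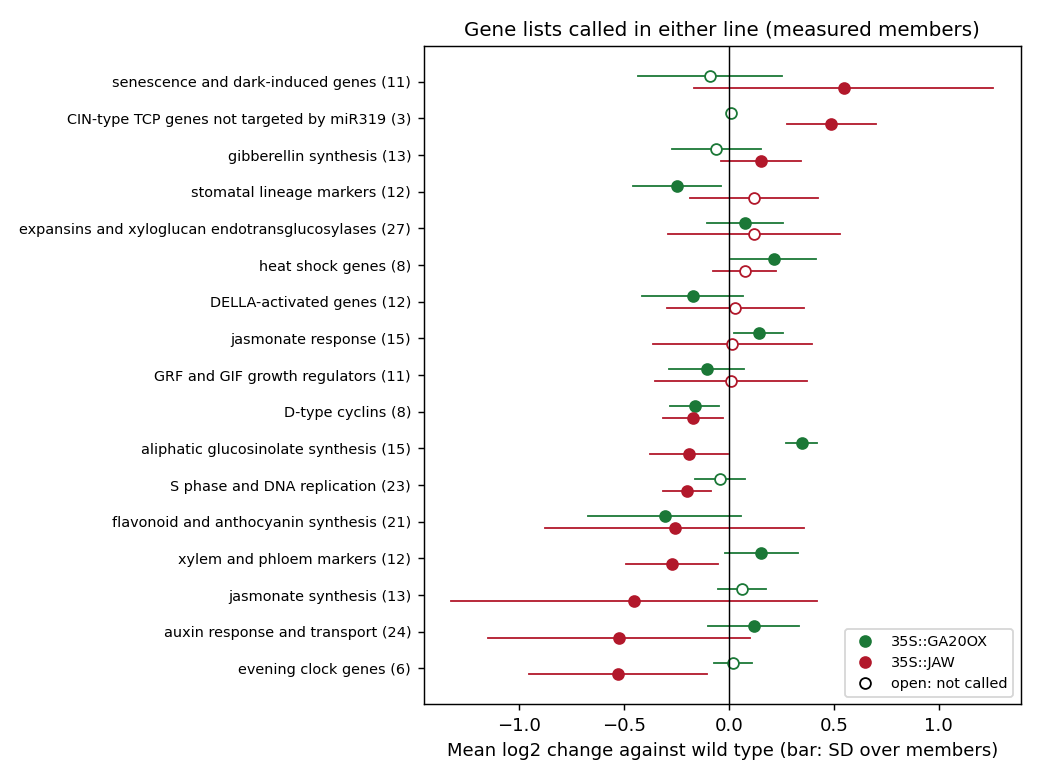
Mean log2 change against wild type (horizontal axis) of each gene list that camera called in either line, with the measured members in parentheses, a point per line (green 35S::GA20OX, red 35S::JAW, open where not called) and a bar of 1 SD over the list's members. The 5 targeted TCP genes, at -2.79 in 35S::JAW, are left out for scale, and aliphatic glucosinolate synthesis lies at 0.35 in 35S::GA20OX and at -0.19 in 35S::JAW.

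The direct comparison of 35S::JAW with 35S::GA20OX tested where the lines differed, with wild type cancelling out. In it, 1394 loci were higher and 1355 lower in 35S::JAW, 104 and 120 of them by at least 2-fold. Beyond GA20OX1 (-7.75 ± 0.09), the lowest in 35S::JAW were ELI3-1 (-4.65 ± 0.06), PCC1 (-3.46 ± 0.39), TCP2 (-3.36 ± 0.07) and AT1G31680 (-3.30 ± 0.09). The highest were AZI1 (3.172 ± 0.386), SWEET1 (2.75 ± 0.07), AT3G16530 (2.64 ± 0.13), AT2G05540 (2.43 ± 0.13) and MEE3 (2.29 ± 0.20).

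Camera called 12 of the 34 lists between the lines, 5 higher and 7 lower in 35S::JAW, and the same 3 lists held with an estimated correlation. The targeted TCP genes had a mean of -2.71, with 5 of 5 lower (5 when adjusted over the list alone, adjusted p = 0.00437 with an estimated correlation). Auxin genes had a mean of -0.64 (adjusted p = 0.0255 with an estimated correlation), with 15 of 24 lower and 1 higher (16 and 2 when adjusted over the list alone), among them SAUR63 at -1.70 ± 0.17. Jasmonate synthesis had a mean of -0.51 and a median of -0.27 (adjusted p = 0.0255 with an estimated correlation), with 6 of 13 lower (6 when adjusted over the list alone). Aliphatic glucosinolate genes were lower in 35S::JAW than in 35S::GA20OX for 12 of 15 members (12 when adjusted over the list alone), with a mean of -0.54 (camera adjusted p = 1.61e-10, and adjusted p = 0.278 with an estimated correlation). FMOGS-OX3 (-0.87 ± 0.11), FMOGS-OX1 (-0.83 ± 0.12), SOT17 (-0.77 ± 0.12) and BCAT4 (-0.73 ± 0.14) led them. Of the 12 stomatal lineage markers 8 were higher and 1 lower in 35S::JAW (9 and 2 when adjusted over the list alone), with a mean of 0.36 (camera adjusted p = 0.000186, and adjusted p = 0.218 with an estimated correlation). TMM had 0.92 ± 0.10, MYB60 0.92 ± 0.12, SPCH 0.92 ± 0.15 and the guard cell channel gene KAT1 -0.65 ± 0.13. Beside them, 6 of the 12 xylem and phloem markers were lower (10 when adjusted over the list alone), including XCP1 at -0.72 ± 0.12 and XCP2 at -0.60 ± 0.10. Their mean was -0.43 (camera adjusted p = 7.62e-06, and adjusted p = 0.218 with an estimated correlation).

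Of the remaining called lists, S phase genes had a mean of -0.16 with 5 lower and 6 when adjusted over the list alone (adjusted p = 0.218 with an estimated correlation). Evening clock genes had -0.55 with 4 lower and 4 when adjusted over the list alone (adjusted p = 0.294 with an estimated correlation). Gibberellin synthesis genes had a mean of 0.21, with GA2, GA3 and GA3OX1 (0.67 ± 0.07) higher and 4 when adjusted over the list alone (adjusted p = 0.135 with an estimated correlation). That list leaves out GA20OX1, which was lower in 35S::JAW by more than any other locus. The DELLA genes RGL1 (-1.02 ± 0.09), RGL2 (-0.93 ± 0.10) and GAI (-0.70 ± 0.07) were lower in 35S::JAW. DELLA-activated genes had a mean of 0.20, 3 higher and 1 lower (5 and 1 when adjusted over the list alone, adjusted p = 0.218 with an estimated correlation), with XERICO at 0.62 ± 0.09. That call was lost without 35S::JAW replicate 1 (adjusted p = 0.079). Senescence and dark-induced genes had a mean of 0.64 with 4 higher and 4 when adjusted over the list alone (adjusted p = 0.435 with an estimated correlation). That call was lost without 35S::GA20OX replicate 2 (adjusted p = 0.22). The CIN-type TCP genes without a miR319 site had a mean of 0.48, with 2 higher and 3 when adjusted over the list alone (adjusted p = 0.279 with an estimated correlation). KNAT1 (-0.82 ± 0.18) and STM (-0.49 ± 0.12), genes of meristem identity, were lower in 35S::JAW, and their list was not called (camera adjusted p = 0.0872, the lowest of the 22 uncalled lists). G2 and M phase genes passed without 35S::GA20OX replicate 2 (mean -0.10, adjusted p = 0.0442). Morning clock genes (mean 0.26) and touch, wound and cold genes (mean 0.57) passed without 35S::JAW replicate 2 (adjusted p = 0.0272 for each). The call of STM was lost with at least 1 array left out (adjusted p up to 0.0655). Mean, median and test differed in sign for cell cycle inhibitors (mean 0.02, median 0.06, test lower) and D-type cyclins (mean -0.008, median 0.006, test lower). They also did for expansins (mean 0.04, median -0.04, test lower), gibberellin perception (mean -0.18, median 0.05), flavonoid (mean 0.05, median -0.001) and brassinosteroid genes (mean 0.03, median -0.05), and none of these 6 lists was called. The number of loci higher in 35S::JAW was 882 without 35S::GA20OX replicate 2, and the number lower was 903 without 35S::JAW replicate 1.

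An F test over the 3 genotypes called 2383 loci (11.5% of those tested), and 1557 without 35S::JAW replicate 1. Of the loci called in both lines against wild type, 7 were higher and 14 lower in both, 14 were higher in 35S::GA20OX and lower in 35S::JAW, and 12 were lower in 35S::GA20OX and higher in 35S::JAW. Independent lists of these sizes would share 1.48, 1.39, 1.35 and 1.52 loci. Both lines were compared with the same 3 wild-type arrays, which cannot be split into parts of at least 2 arrays, so part of the excess among loci that moved alike may come from those arrays. In 100 simulations of unchanged lines against shared simulated controls the median number was 0 in each direction, with up to 327 loci higher in both, 433 lower in both and 0 opposite. The correlation of log2 changes across loci was 0.057, against a simulated median of 0.49 (range -0.372 to 0.96), and the covariance was 0.00201 against 0.00391, a difference of -0.0019. The simulated noise came from only 6 residual effects, so these ranges and maximum counts may be too wide. AT5G22460 rose in both lines (1.097 and 1.55), as did AT4G29270 (0.63 and 0.68), the purple acid phosphatase gene PAP8 (0.68 and 0.57), AT2G21220 (0.47 and 0.98) and MLP28 (0.51 and 0.44). AT3G20370 (-1.47 and -1.59), AT4G36700 (-1.35 and -2.03), UGT75C1, AT1G52100 (-0.82 and -0.76) and GSTF12 fell in both. AT4G17470 rose by 1.45 in 35S::GA20OX and fell by 1.26 in 35S::JAW, and AT4G23680 rose by 1.09 and fell by 1.52. AT3G16530 fell by 1.02 and rose by 1.63, and AT3G44970 fell by 0.93 and rose by 1.09. With an intensity trend and robust prior 24 loci were higher in both, 27 lower in both and 59 opposite. Without the dimmest 40% of loci 42 were opposite, with array weights 13 were higher in both, and at an adjusted p of 0.01 the counts were 1, 2 and 6. With at least a 2-fold change they were 1, 2 and 3. The calls of AT4G29270, PAP8, AT2G21220 and MLP28 in 35S::GA20OX were each lost with at least 1 array left out. The loci higher in both, lower in both and opposite were 2, 8 and 11 without wild type replicate 1, 5, 8 and 11 without replicate 2, and 1, 2 and 8 without replicate 3. They were 1, 6 and 15 without 35S::GA20OX replicate 1, 6, 5 and 14 without replicate 2, and 4, 7 and 14 without replicate 3. They were 3, 10 and 19 without 35S::JAW replicate 1, and 4, 8 and 21 without replicate 3.

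**Figure D3:**
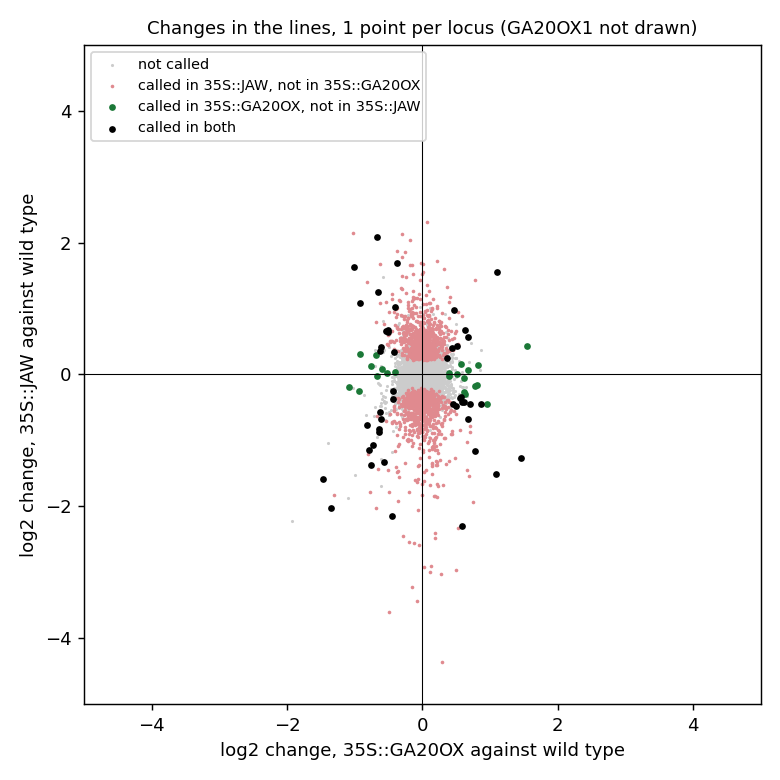
Log2 change of each locus in 35S::GA20OX (horizontal axis) and in 35S::JAW (vertical axis) against wild type, with 1 point per locus, coloured by the line in which it passed an adjusted p of 0.05, and GA20OX1 left out for scale. The black points, called in both lines, lie in all 4 quadrants, and the spread along the vertical axis is wider, reaching -4.36 for ELI3-1.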

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

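The tests of vascular share and of an intensity-dependent shift were chosen after the glucosinolate result had been seen. With camera's preset correlation, 3 gene lists were called in both lines against wild type in opposite directions and called again in the direct comparison. The direct comparison is the difference between the changes of the lines, in which opposite changes add up. Its calls are therefore no separate evidence, for lists and for single loci. The mean log2 difference between 35S::JAW and 35S::GA20OX was -0.641 for auxin response and transport, -0.538 for aliphatic glucosinolate synthesis and -0.426 for xylem and phloem markers. With an estimated correlation the auxin call was lost in 35S::GA20OX (adjusted p = 0.279), and the vascular call in 35S::GA20OX (0.361), in 35S::JAW (0.349) and between the lines (0.218). With an estimated correlation the glucosinolate call was lost in 35S::GA20OX (0.252), in 35S::JAW (0.626) and between the lines (0.278). Single arrays also ended calls: wild type replicate 3 or 35S::GA20OX replicate 1 that of auxin genes in 35S::GA20OX (adjusted p up to 0.172), 35S::GA20OX replicate 1 or 3 that of vascular markers there (up to 0.119), and wild type replicate 3 that of glucosinolate genes in 35S::JAW (0.0636). In addition, 26 loci were called in both lines in opposite directions and called between the lines. They include SWEET1, PR5, GA20OX1 and SAUR27.

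The aliphatic glucosinolate genes had a mean of 0.35 in 35S::GA20OX (adjusted p = 0.252 with an estimated correlation) and of -0.19 in 35S::JAW (adjusted p = 0.626 with an estimated correlation), which became 0.23 and -0.31 without wild type replicate 2, and 0.42 and -0.12 without wild type replicate 3. An intensity-dependent shift left between arrays after RMA is argued against by cyclic loess, after which at least 101.2% of the mean change was left in each line, with the list called in both. Cyclic loess was run on quantile-normalised values, so only a shift that RMA had left could be seen. In 35S::GA20OX the phloem markers had a mean of 0.00, which lay 0.228 ± 0.106 (SE over markers) below that of the xylem markers, just over 2 SE. That met the outcome set as counting against another share of vascular tissue as the cause. The SE takes the markers as independent, although their estimated correlation was 0.237, so this test cannot decide the question. In 35S::JAW the difference between xylem and phloem markers was -0.176 ± 0.118 with both below 0, so that lower glucosinolate genes and a lower vascular share cannot be told apart there with 4 phloem markers. The genotypes themselves remain an open, biological explanation.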

How the results depend on the processing

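None of the 231 called values of named genes and none of the 35 list calls changed direction in the alternatives run for them. Where arrays do not overlap, leaving 1 out cannot reverse a difference. That held for 69 of 69 called loci in 35S::GA20OX, 1725 of 1729 in 35S::JAW and 2738 of 2749 between the lines. The unchanged direction is therefore little evidence of stability. The lists were run with cyclic loess, the replicate block, each array left out, an estimated correlation and fry, and the direction of other loci was not followed. The alternatives, all planned in advance, gave 215 values of counts of loci, overlaps and lists. Of these, 144 lay within 1.5 times the reported value and 71 did not. A stricter threshold lowers a count by construction, and otherwise the cause was not tested. With at least a 2-fold change, the loci higher and lower were 5 and 4 in 35S::GA20OX, 67 and 101 in 35S::JAW, 104 and 120 between the lines and 170 in the F test, and the overlaps were 1 both higher, 2 both lower and 3 opposite. At an adjusted p of 0.01 they were 8 and 7, 443 and 423, 684 and 687, 1172, and 1, 2 and 6. Without the dimmest 40% of loci, 55 were higher and 53 lower in 35S::GA20OX and 42 opposite between the lines. With an intensity trend and robust prior, 102 were higher and 103 lower in 35S::GA20OX, and the overlaps were 24 both higher, 27 both lower and 59 opposite. With array weights 13 loci were higher in both lines. An estimated correlation left 0 lists in 35S::GA20OX, 3 in 35S::JAW and 3 between the lines, and fry gave 6 in 35S::GA20OX.

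With each array left out, the loci higher ranged from 11 to 37 and lower from 11 to 42 in 35S::GA20OX, from 548 to 876 and 526 to 865 in 35S::JAW, and from 882 to 1373 and 903 to 1356 between the lines. The F test called 1557 to 2279 loci. The overlaps ranged from 1 to 6 both higher, 2 to 15 both lower and 8 to 27 opposite. The lists called ranged from 7 to 12 in 35S::GA20OX, with 7 without 35S::GA20OX replicate 1, from 9 to 13 in 35S::JAW and from 11 to 14 between the lines. The lowest counts against wild type came without wild type replicate 3 (11 and 11 in 35S::GA20OX, 548 and 526 in 35S::JAW).

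The replicate numbers did not clearly pair the arrays: 4 of 9 pairs of arrays with the same number had deviations from their genotype means that correlated above 0.1 (range -0.102 to 0.251), and 3 of 9 arrays correlated best with their own number. Weak pairing is not ruled out, with 0.153 in replicate 1 and 0.251 in replicate 2 between the transgenic lines. With the replicate number as a block, the calls were 74 in 35S::GA20OX, 1811 in 35S::JAW and 2739 between the lines, and the lists of expansins in 35S::GA20OX, flavonoid genes in 35S::JAW and DELLA-activated genes between the lines were no longer called. The block also ended the calls of RGL2 (adjusted p = 0.052), PR5 (0.0744), AT2G21220 and MLP28 in 35S::GA20OX and of GA3 in 35S::JAW (0.0678). Of 231 called values of named genes, 157 kept their call in every fit and 74 lost it in at least 1, 71 of them with an array left out. Of 35 list calls, 6 were kept in every fit and 11 were lost with an array left out, and some lists that were not called passed with an array left out, root markers among them. Centring on array medians moved the share of higher loci from 52.2% to 58.1% in 35S::JAW. The mean of a gene's probe sets was not run, since the table has 1 row per locus. Signal over background could not be judged from these values.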

Other observations

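The tests of single wild-type arrays, and their split by line, were chosen after the values they measure had been seen. The lists of starvation-induced and ER body genes were drawn up after related genes had been seen, and were tested on members not looked at before. Of 13 genes known to rise when sugar runs short that had not been looked at before, 5 rose in 35S::JAW, with a mean log2 change of 0.411 ± 0.111 (SE over members), among them the beta-xylosidase gene BXL1 (1.27 ± 0.22), DIN10 (0.94 ± 0.25), the kinase subunit gene AKINBETA1 (0.85 ± 0.13) and TPS10 (0.36 ± 0.09). In 35S::GA20OX none of them passed, and their mean was -0.241 ± 0.03. With an estimated correlation neither list test passed (adjusted p = 0.295 in 35S::JAW and adjusted p = 0.275 in 35S::GA20OX). Between the lines 9 of the 13 were higher in 35S::JAW (camera adjusted p = 1.7e-08, and adjusted p = 0.275 with an estimated correlation). The 73 chloroplast-encoded loci had a median log2 change of 0.03 in 35S::GA20OX and -0.03 in 35S::JAW, and 1 of them was called, lower in 35S::JAW.

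In 35S::JAW 4 of 6 evening clock genes fell (adjusted p = 0.349 for the list with an estimated correlation) and 4 of 11 senescence and dark-induced genes rose (adjusted p = 0.403 with an estimated correlation, and 0.0675 with the preset one without wild type replicate 1). Harvest at another time of day or in another light could give both, and the rise of the other starvation-induced genes by 0.411 goes with it. It would also move the morning clock genes, whose mean was 0.07 ± 0.05 over 4 genes, within 2 SE of 0, and 0.01, 0.19 and 0.02 without 35S::JAW replicate 1, 2 and 3. A harvest difference and an effect of the genotype cannot be told apart, because no harvest time is labelled and 4 genes are few.

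Of 21 flavonoid and anthocyanin genes 5 fell in each line, which share their wild-type arrays, and the list calls were lost with an estimated correlation (adjusted p = 0.168 in 35S::GA20OX and adjusted p = 0.408 in 35S::JAW). The list median was -0.26 in 35S::GA20OX, with 6 positive members, and only -0.08 in 35S::JAW, with 8. The low mean in 35S::JAW is thus not a shift of the whole pathway. Noise of shared controls, of the size seen within genotypes, is argued against by simulation. With all arrays redrawn, 0 of 100 draws of unchanged lines gave means as low in both lines, where the lowest simulated means were -0.14 and -0.129. Over both lines, 5 of the 6 fits that left out 1 wild-type array kept the call. Without wild type replicate 3 the mean in 35S::JAW went only from -0.26 to -0.22, while the camera adjusted p went from 0.0258 to 0.0502, just past the threshold. That loss met the outcome set as counting for a single high wild-type array. Most of the change was left, so wild type replicate 3 as a contributor stays open there. In 35S::GA20OX the list stayed called in 3 of 3 such fits, with means from -0.35 to -0.27, which argues against a single high wild-type array there. The genotypes stay open, too, as a biological explanation.

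JAL23, and the neighbouring genes BGLU18 (AT1G52400, 0.57 ± 0.08) and TSA1 (AT1G52410, 0.62 ± 0.09), genes of the ER body, a store of glucosinolate-cleaving enzymes, were called higher in 35S::GA20OX. The hypothesis that ER body and myrosinase-binding genes follow the glucosinolate genes was tested on 9 members not looked at before. Their mean was -0.04 ± 0.09 (SE over members) in 35S::GA20OX (camera adjusted p = 0.63), against 0.35 for the glucosinolate genes, and -0.04 in 35S::JAW (camera adjusted p = 0.562). Of the 9, JAL35 rose in 35S::GA20OX (0.52 ± 0.07) and MVP1 fell in 35S::JAW (-0.24 ± 0.06), both in the direction of the hypothesis. As a set the members did not pass in either line, the outcome named in advance as counting against it.

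The 6 arrays of each comparison can be split in 10 ways, too few for a share under 0.05. The real split was the 1 with the most calls in 35S::GA20OX (69, highest other 4), in 35S::JAW (1729, highest other 0) and between the lines (2749, highest other 0). Of the 280 splits of the 9 arrays into 3 groups, 100 were scored, the real one among them. Of these 1, the real one, gave as many loci in the F test (2383), a share under 0.05. That argues against a random grouping for that count but does not exclude it. The highest other split gave 1693. It kept the 35S::JAW arrays together and exchanged 1 array between wild type and 35S::GA20OX, so much of the count goes with 35S::JAW.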
